A study of Bos taurus with 21 samples.

How the data were processed

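Heifer (Bos taurus) hypothalamus was profiled by single-read, polyA-selected mRNA sequencing in 21 libraries, which the labels number as 7 replicates in each of 3 groups. Control heifers received 1.2 Mn and ovulated. Restricted heifers received 0.4 Mn, Mn being the labels' unit of feeding level, and were divided by outcome into those that stopped ovulating (restricted anovulatory, RA) and those that kept ovulating (restricted ovulatory, RO). Tissue was taken after 18 days of differential feeding. Groups were taken from the sample titles. Nothing beyond the replicate numbers says that the 7 libraries of a group came from separate animals, so the p-values measure the spread between these samples.

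The authors deposited 1 table per library of raw read counts per gene, which are whole numbers with no normalization and no row for unassigned reads. The submitters' processing notes name CASAVA 1.4, Bowtie, SAMtools and HTSeq, without roles or settings. The genome build, the annotation release, the treatment of duplicate or multiply mapped reads and the strand setting are not given in the sources used here. All 21 tables list the same 22984 Ensembl-style gene identifiers. The tables do not pair identifiers with names, and the reference gene table used here held no Ensembl identifiers, so 0 of 22984 identifiers were matched to a symbol. Genes are therefore given by identifier, with no coordinates. The 31 lists of pathway and cell type genes that had been fixed before the data were examined, among them appetite peptides, the GnRH and kisspeptin system and markers of pituitary, glia and blood, were not tested, and neither was a correction for GC content.

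Total counts ran from 3379050 to 4476586 per library (median 3932234). Genes were kept by edgeR's filterByExpr with its defaults (a minimum count of 10, scaled to depth, in at least 7 libraries, and a total of at least 15), which left 13435 genes holding 99.75% of the counts. The median count of a tested gene in a library was 171. Counts were scaled by the trimmed mean of M-values (TMM) and tested with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood F-test on a model of 3 group means fitted to all 21 libraries, so that the groups shared one estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were derived as the fold change divided by the square root of its F statistic, and 95% intervals used the fit's degrees of freedom. CPM (counts scaled to a common library size) and log2 CPM (prior count of 2) were computed here from the counts. The rule fixed for naming genes required symbols. In its place the 2 genes with the smallest p-values in each direction are given per comparison.

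The deposited file names carry a token that reads as a sequencing date. Its 4 values, called runs A to D here in sorted order, were treated as technical batches. Run A held 1 library of each group. Run B held 6 RO libraries and 1 control. Run C held 5 controls and 2 RA libraries. Run D held 4 RA libraries and no other group. Group and run were therefore largely confounded, most of all between RA and RO, whose libraries shared only run A. Each comparison was also fitted with run as a covariate. Since run D held RA alone, its 4 libraries do not bear on the fold changes of RA in that fit. Those fold changes rest on the 3 RA libraries of runs A and C. The difference between run D and runs A and C was tested inside the RA group.

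Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter and a stricter filter (at least 5 CPM in at least 7 libraries), DESeq2 1.42.0, limma-voom 3.58.1 with sample quality weights, a fit to the 2 compared groups alone, run as a covariate, only the runs that hold both groups, the replicate number as a block, a threshold of 0.1 and leaving out each replicate of the compared groups. The fit to the runs that hold both groups also had run as a covariate. Leaving out replicates of the third group, splitting the controls, the simulated overlap of low p-values, the exact multivariate test and the pooled contrasts were added after the data were seen. Replicate numbers did not pair the samples. Deviations from the group means correlated between same-numbered libraries by -0.0448 on average over 21 pairs, with 4 pairs above 0.1. No 2 libraries agreed within sampling noise, for which the chi-square of counts per degree of freedom is about 1. It was at least 2.16 over all 210 pairs of libraries and at least 2.24 within a group.

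The test was checked on simulated counts for the same 13435 genes, drawn with the observed means, dispersions and library sizes. Genes were simulated independently of each other and without run effects. For RA against RO, with 200 genes changed, 57.0% of 1.5-fold and 83.3% of 2-fold changes passed, and 6.03% of the calls were false. With no gene changed, 0 genes passed on average over 3 simulations. The same figures with 200 changed genes were 62.0% and 86.3% for RA against control and 64.7% and 82.0% for RO against control. The multivariate test took the share of the squared distance between libraries (log2 CPM of all tested genes) that lay between 2 groups and compared it with every arrangement of the labels. Any arrangement puts some of the distance between groups, so the share alone does not measure an effect.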

Results

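The data covered the hypothalamus, the brain region that releases gonadotropin-releasing hormone and regulates feeding, of heifers in 21 libraries, with 7 each from well-fed controls, restricted anovulatory (RA) and restricted ovulatory (RO) animals. The total count per library was 3916686 ± 150715 in controls, 4012398 ± 345141 in RA and 3886529 ± 274200 in RO (SD, n = 7 each). None of the 3 pairwise differences in depth exceeded the spread between libraries (two-sided exact permutation tests over 3432 arrangements, p = 0.506 for RA against control, 0.809 for RO against control and 0.463 for RA against RO, with Benjamini-Hochberg adjusted values from 0.760 to 0.809). Between 15877 and 16391 genes had at least 1 count in a library. The biological coefficient of variation common to all tested genes was 18.3%. The libraries did not form separate clusters by group on the first 2 principal components of log2 CPM, and control replicate 5 lay apart from the other 20 libraries. Its mean correlation with the other controls was 0.927, against 0.956 to 0.966 for the other 6 controls.

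**Figure D1:**
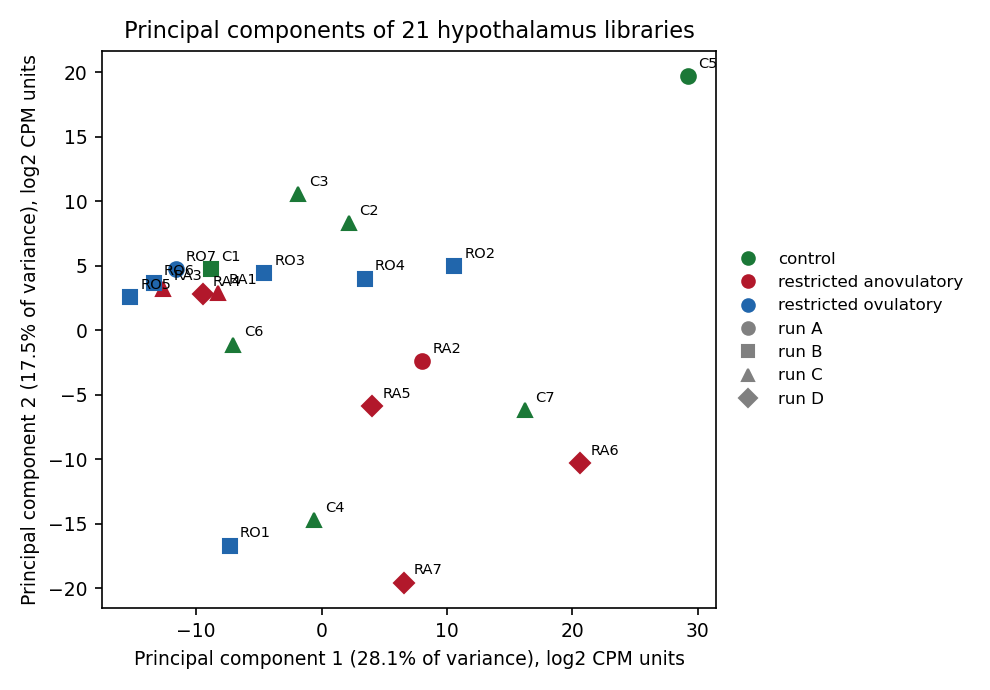
Principal components 1 and 2 (28.1% and 17.5% of the variance, in log2 CPM units) of the 500 most variable tested genes; each point is a library, coloured by group, shaped by sequencing run and labelled by group (C, control) and replicate number. The groups overlap, and control replicate 5 lies at the upper right.

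The comparison of RA with RO asked which hypothalamic genes differed between animals on the same restricted diet that stopped or kept ovulating. Without run as a covariate it had the most genes with a low p-value of the 3 comparisons, and with run as a covariate the fewest (291, against 769 for RA against control and 469 for RO against control). No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test (smallest adjusted p 0.0824), but 2783 of 13435 genes had an unadjusted p under 0.05, where 672 would be expected by chance. Of these 1172 were higher and 1611 lower in RA. Limma-voom with quality weights also called 0 genes, with 2732 under an unadjusted 0.05. DESeq2 called 474, of which 124 were higher and 350 lower in RA. At an adjusted p of 0.1 in edgeR's test 299 genes passed, 61 of them higher and 238 lower in RA, with a median absolute log2 fold change of 0.42 and a range of 0.14 to 1.78. Of these 299 genes, 284 were among the 474 that DESeq2 called. Leaving out 1 library brought 399 genes under an adjusted 0.05 in edgeR's test without RO replicate 4, 21 without control replicate 7, 17 without RA replicate 3 and 1 without RO replicate 7.

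The gene with the smallest p-value was ENSBTAG00000022548. It measured 93.3 ± 19.3 CPM in RA, 173.9 ± 26.9 in RO and 112.7 ± 27.6 in controls (SD, n = 7 each), a log2 fold change of -0.90 between RA and RO (SE 0.15, edgeR adjusted p = 0.0824). ENSBTAG00000044427 measured 6.97 ± 2.25 CPM in RA, 19.7 ± 8.95 in RO and 9.56 ± 2.46 in controls, with a log2 fold change of -1.50 (SE 0.27, edgeR adjusted p = 0.0917). On the higher side, ENSBTAG00000014912 measured 72.6 ± 17.3 CPM in RA, 43.6 ± 5.92 in RO and 67.0 ± 16.3 in controls (log2 fold change 0.74, SE 0.16, edgeR adjusted p = 0.0927). ENSBTAG00000015718 measured 21.4 ± 3.77 CPM in RA, 13.5 ± 3.54 in RO and 15.6 ± 1.58 in controls (log2 fold change 0.67, SE 0.15, edgeR adjusted p = 0.0927). For each of these 4 genes, 7 of 7 RA libraries lay beyond the RO median in the direction of the group difference. The genes were picked on these same libraries. With run as a covariate the log2 fold changes kept their signs at -0.40 for ENSBTAG00000022548, -0.62 for ENSBTAG00000044427, 0.55 for ENSBTAG00000014912 and 0.81 for ENSBTAG00000015718, and the edgeR adjusted p was 0.9999 for each.

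**Figure D2:**
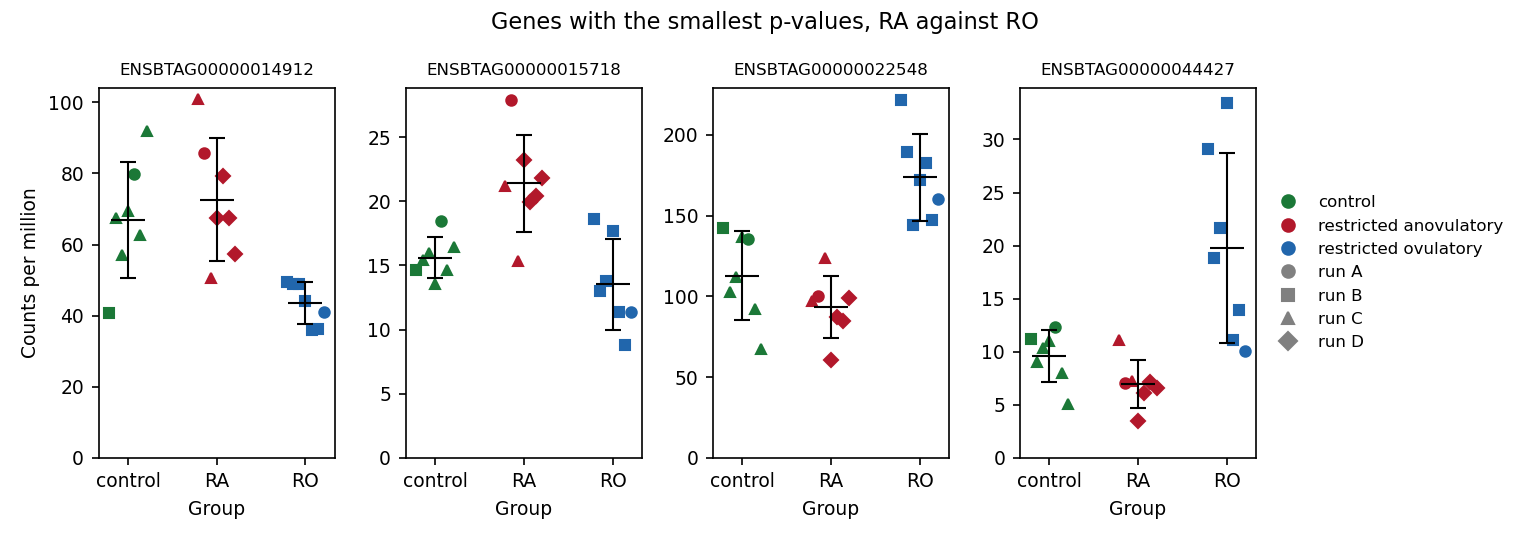
CPM (vertical axis, from 0) of the 2 genes with the smallest p-values in each direction between RA and RO; points are libraries, coloured by group and shaped by sequencing run, and the black bar and whiskers are the group mean and SD (n = 7). For ENSBTAG00000022548 the RO mean is 173.9 CPM, against 93.3 in RA and 112.7 in controls.

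Group and sequencing run were confounded in this comparison, since RA and RO libraries shared only run A, with 1 library of each and so no test within it. With run as a covariate 0 genes passed in edgeR's test and 291 had an unadjusted p under 0.05, against 672 expected by chance. Other splits of these 14 libraries, fitted without run, gave a median of 384, so 291 does not show a lack of low p-values. With run in the fit, the median standard error of the log2 fold change went from 0.125 to 0.226. The RA side of that fit rested on the 3 RA libraries outside run D, since run D held no other group. The fold changes of 298 of the 299 genes kept their sign in that fit, and their median size in the original direction went from 0.42 to 0.26. Both fits contain the libraries on which the 299 genes were picked. Across all genes, 14.1% of the squared distance between the 14 RA and RO libraries lay between the groups (exact permutation test over 3432 arrangements, p = 0.021, adjusted over the 3 comparisons 0.0629). The 2 arrangements possible within runs allow no p under 0.5. The RA and RO libraries did not overlap for 89 genes, where chance gives 7.83 on average (2 of 3432 arrangements per gene). The count was 9 for RA against control and 14 for RO against control. Genes are not independent and the spread of this count over splits was not computed, so the 89 genes are not a test.

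The comparison of RA with control set animals that stopped ovulating on the restricted diet against well-fed, ovulating animals. No gene passed in edgeR's test (smallest adjusted p 0.532), and 1244 genes had an unadjusted p under 0.05 against 672 expected by chance, 664 of them higher and 580 lower in RA. DESeq2 and limma-voom also called 0 genes, with 1370 and 1563 under an unadjusted 0.05. Without control replicate 7, edgeR's test still called 0 genes and 2141 had an unadjusted p under 0.05. The smallest edgeR adjusted p fell to 0.1005 without control replicate 2, the lowest of the 21 fits that left out 1 library. ENSBTAG00000021312 measured 197.5 ± 13.9 CPM in RA and 164.3 ± 11.04 in controls (log2 fold change 0.27, SE 0.067, SD and n = 7 as above), and ENSBTAG00000031579 measured 68.6 ± 8.92 and 51.6 ± 7.58 (log2 fold change 0.41, SE 0.11). In the other direction, ENSBTAG00000019770 measured 3.47 ± 1.67 CPM in RA and 9.01 ± 3.43 in controls, with control replicate 2 below the other 6 controls, a log2 fold change of -1.37 (SE 0.30). ENSBTAG00000010572 measured 60.0 ± 6.53 CPM in RA and 77.3 ± 9.33 in controls (log2 fold change -0.37, SE 0.096). The edgeR adjusted p was 0.532 for each of the 4. The log2 fold changes with run as a covariate, in the order given, were 0.25, 0.39, -1.66 and -0.29. With run as a covariate 0 genes passed and 769 had an unadjusted p under 0.05. In the runs that held both groups, A and C, a fit with run as a covariate passed 0 genes, and 1217 had an unadjusted p under 0.05. Run A held 1 library of each group there, and run C held 2 RA libraries and 5 controls. The share of the squared distance between the groups was 8.60% (exact permutation p = 0.256, and 0.452 over the 42 arrangements within runs).

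The comparison of RO with control addressed the restricted diet among animals that all ovulated. No gene passed in edgeR's test (smallest adjusted p 0.622), and 864 genes had an unadjusted p under 0.05, 296 of them higher and 568 lower in RO. DESeq2 and limma-voom called 0 genes, with 977 and 682 under an unadjusted 0.05. ENSBTAG00000022548 and ENSBTAG00000044427, the 2 genes lower in RA with the smallest p-values in the comparison of RA with RO, measured 173.9 ± 26.9 and 19.7 ± 8.95 CPM in RO against 112.7 ± 27.6 and 9.56 ± 2.46 in controls, with log2 fold changes of 0.62 (SE 0.15) and 1.04 (SE 0.26). In the fit with run as a covariate these were 0.36 and 0.54, and 6 of 7 RO libraries were in run B. In run A, with 1 library each, ENSBTAG00000022548 measured 160 CPM in RO and 135 in control. ENSBTAG00000044427 measured 10.1 CPM in RO and 12.3 in control there, against the direction of the group difference. ENSBTAG00000042959, a gene near the detection floor, measured 0.852 ± 0.687 CPM in RO, 3.11 ± 1.16 in controls and 3.01 ± 1.36 in RA, a log2 fold change of -1.82 between RO and control (SE 0.40). ENSBTAG00000037717 measured 14.3 ± 3.52 CPM in RO and 22.6 ± 4.07 in controls (log2 fold change -0.66, SE 0.16). The log2 fold changes with run as a covariate were -2.10 for ENSBTAG00000042959 and -0.42 for ENSBTAG00000037717. The edgeR adjusted p was 0.622 for each of the 4. With run as a covariate 0 genes passed and 469 had an unadjusted p under 0.05. In runs A and B, which held both groups, a fit with run as a covariate passed 0 genes, and 412 had an unadjusted p under 0.05. The only controls in that fit were replicate 5 in run A, which lay apart from the other libraries, and replicate 1 in run B. The fit therefore had little power. The share of the squared distance between the groups was 8.03% (exact permutation p = 0.361, and 0.357 over the 14 arrangements within runs, which allow no p under 0.0714).

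**Figure D3:**
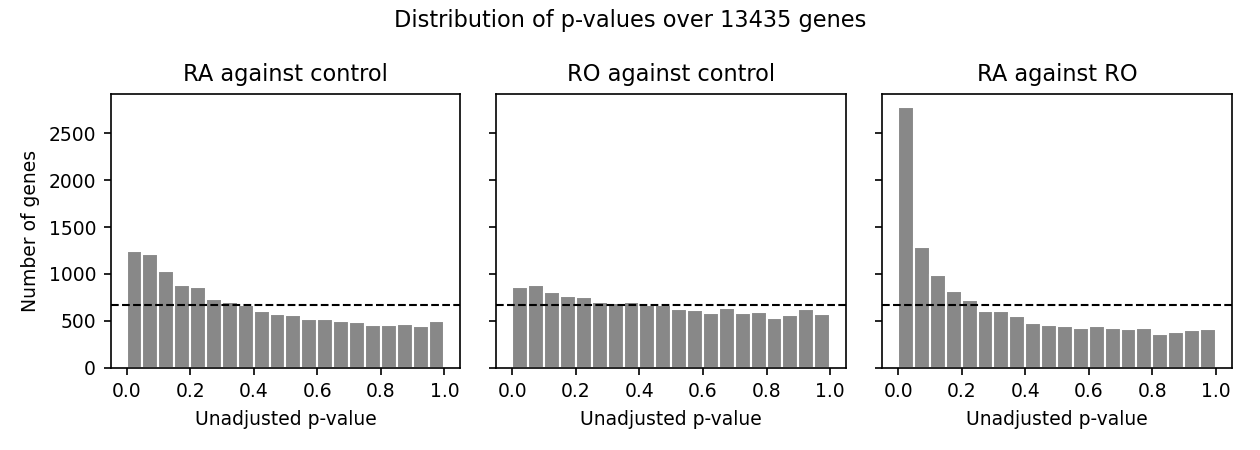
Number of genes (vertical axis) by unadjusted p-value (horizontal axis, bins of 0.05) in edgeR's test for each comparison over 13435 genes; the dashed line is the number per bin with no difference, 672. The lowest bin holds 2783 genes for RA against RO, 1244 for RA against control and 864 for RO against control.

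The replicates bounded the size of most differences. For RA against control, 10073 genes (75.0%) had a 95% interval of the fold change that lay entirely within 1.5-fold in either direction, and 93.3% lay within 2-fold. The corresponding shares were 76.4% and 93.6% for RO against control and 69.7% and 91.3% for RA against RO. These intervals rest on the spread between libraries without run as a covariate. Fitted differences above 2-fold were seen for 101 genes in RA against control, 87 in RO against control and 70 in RA against RO, and none of them passed an adjusted p of 0.05 in edgeR's test. DESeq2 called at least 1 of the 70, ENSBTAG00000044427 (DESeq2 adjusted p = 0.000304).

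The fold changes of the 2 restricted groups against control were then set against each other. Across 13435 genes, which are not independent replicates, the fold changes of RA against control and RO against control correlated with r = 0.191. Both comparisons use the same controls, and unchanged groups that shared 1 set of simulated controls gave a mean r of 0.498 (range 0.469 to 0.523 over 100 simulations). Genes were simulated independently of each other and without run effects, so this range is likely too narrow. It cannot show whether the observed r lies outside what unchanged groups would give. The covariance was 0.00757, against 0.018 in the simulations, a difference of -0.0104. With the controls split so that each comparison had its own, r was -0.438 when RA was set against control replicates 1 to 3 and -0.151 when it was set against replicates 4 to 7. Only this division of the controls was tried, so the negative values do not show opposite responses. Leaving out 1 library moved r between 0.025 (without control replicate 5) and 0.304 (without RO replicate 5). At an unadjusted p under 0.05, 27 genes were higher and 72 lower in both comparisons, and 8 had opposite signs. Such simulated groups put through edgeR's test shared a mean of 72.9 higher (range 53 to 93 over 20 simulations) and 61.2 lower (44 to 78), with 0.7 of opposite sign (0 to 2). The simulated lists were shorter, with means of 645 and 653 genes against the observed 1244 and 864, so these counts are not directly comparable. Independent lists of the observed sizes would share 14.6 and 24.5.

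Inside the RA group, the 4 libraries of run D were compared with the 3 of runs A and C as a check on the runs. No gene passed in edgeR's test (smallest adjusted p 0.611), and 1030 of 13380 genes had an unadjusted p under 0.05, against 669 expected by chance. DESeq2 called 10 genes, with 925 under an unadjusted 0.05. Without RA replicate 4, 60 genes passed in edgeR's test and 2031 had an unadjusted p under 0.05, and without RA replicate 3, 486 did. The share of the squared distance among these 7 libraries that lay between the runs was 20.7% (exact permutation test over 35 arrangements, p = 0.2).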

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

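The tests on control replicate 5 in this part were chosen after its position had been seen. Across 45 sets of 7 values, 5 stood out because their most extreme library lay farther from its neighbour than Dixon's 95% limit allows; chance alone picks out about 1 in 20 such sets. Values for single genes are in log2 CPM.

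Control replicate 5 stood out for its mean correlation of 0.92712 with the other controls, whose own values were 0.956 to 0.966, and for the share of its counts in its 10 most abundant genes, 1.12% against 1.24% to 1.29% in the other controls. Low depth is argued against, since its total of 3849085 counts lay within the 3698427 to 4078108 of the other controls. A fault common to run A is argued against, since the other libraries of that run had mean correlations with their own groups of at least 0.96564, inside the range of those groups. Its mean correlation with RA and with RO reached only 0.9225, below the 0.958 of the lowest RA or RO library with its own group. This cannot decide on an exchange of labels with a restricted group, since a library apart from every group scores low under any label. Mean correlation also did not mark the group in other libraries. Control replicate 1 correlated better with RO (0.973) than with the other controls (0.962). An exchange therefore stays open. A difference in dissected tissue, in RNA quality or in the animal itself stays open. None of these was tested, and tissue composition could not be without gene names.

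ENSBTAG00000042959 measured 2.62 in control replicate 5, against 1.46 to 1.88 in the other controls. For ENSBTAG00000019770, control replicate 2 was at 1.67, against 2.99 to 3.87 in the other controls. ENSBTAG00000031579 stood at 6.46 in RA replicate 7, against 5.92 to 6.13 in the other RA libraries.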

How the results depend on the processing

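Leaving out libraries of the third group and splitting the controls were alternatives chosen after seeing the data. For RA against control and RO against control, edgeR's count of 0 genes held under all 10 other settings run (scaling, filters, DESeq2, limma-voom, the 2 groups alone, run as a covariate, shared runs, replicate block), at a threshold of 0.1 and without any 1 of the 21 libraries. Unadjusted p-values under 0.05 ranged over these settings from 769 to 2141 genes for RA against control (2141 without control replicate 7) and from 412 to 1204 for RO against control. For RA against RO the count was 0 under RLE and upper-quartile scaling, both filters, limma-voom, run as a covariate and the replicate block. It was 474 with DESeq2, 1 with the 2 groups alone and 299 at a threshold of 0.1. Leaving out 1 library gave 0 to 399 genes: 399 without RO replicate 4, 21 without control replicate 7, 17 without RA replicate 3 and 1 without RO replicate 7. The cause of these differences was not tested. A fit to the runs that hold both RA and RO was not run, since run A has 1 library of each, and neither was the GC correction. The replicate block gave 0 genes in each comparison, with 1093, 655 and 2502 under an unadjusted 0.05 (RA against control, RO against control, RA against RO), and 3 of 21 libraries correlated best with a library of their own number. The run difference within RA was 10 genes with DESeq2 and 0 to 60 leaving out 1 library. The correlation of the fold changes of RA and RO against control reversed to -0.438 and -0.151 with the controls split. The shared controls no longer add to it there, which by itself would not make it negative. Only this division was tried, and control replicates 5 and 7 both fell among replicates 4 to 7. The fold changes of the named genes kept their sign in all 71 combinations of gene and setting. These settings refitted the libraries on which the genes were picked, so the shared sign is weak evidence. In 5 of the 71 combinations, all for RA against RO, the gene passed the threshold, 4 with DESeq2 and 1 with the 2 groups alone. At this depth the simulations with 200 changed genes recovered 57.0% to 64.7% of 1.5-fold changes, and smaller changes were not simulated. They had no run effects and were fitted without run, so recovery of a group difference apart from run was not measured.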

Other observations

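The tests of runs in general and of run B were chosen after the results were seen, as were the pooled contrasts and the signed scores. On the axis from the RO mean to the RA mean over all tested genes, with the controls' mean set to 0, RA scored 15.4 ± 9.94 and RO -14.0 ± 13.3, and the controls, which did not enter the axis, spread by an SD of 11.3 (n = 7 each). The highest control, replicate 7, scored 23.2 and the next 1.93. RA and RO are apart on this axis by construction, and another group with no change of its own would also be expected about midway between them. Pooling the 2 restricted groups against control, which follows the diet label, gave 0 genes in edgeR's test and 639 with an unadjusted p under 0.05, below the 672 expected by chance (smallest adjusted p 0.981). That contrast with run as a covariate gave 0 genes and 920, above the number expected by chance. Neither count was set against splits of the libraries, so neither shows a lack or an excess of low p-values. Setting RA against both ovulatory groups, which follows the ovulation label, gave 0 genes and 2524 under an unadjusted 0.05 (smallest adjusted p 0.177), or 394 with run as a covariate.

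The excess of low p-values between RA and RO was weighed against chance, depth and sequencing run. Chance is argued against but not settled: 2 of 100 splits of the 14 libraries, the real one included, gave as many genes, with 2783 for the real split and 3378 for the highest other, which exchanged RA replicate 2 and RO replicate 4. That share is not adjusted for the 3 comparisons, and the multivariate test of the same groups had an adjusted exact permutation p of 0.0629. Depth is argued against, since 2693 genes were under an unadjusted 0.05 after every library was thinned to 3379050 counts. Sequencing runs in general cannot be told apart from the groups, because RA and RO share only run A, and with run as a covariate 291 genes were under an unadjusted 0.05. Run-specific accounts and the ovulatory response itself both stay open, the latter untested apart from run.

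Values that bear on single runs went both ways. For 212 genes picked from the RA libraries of run D and RO replicates 1 to 3, the median signed log2 difference was 0.519 there and 0.287 between the other RA libraries and RO replicates 4 to 7 (exact one-sided permutation p = 0.0571 over 35 arrangements). On these genes the RA libraries outside run D differed from the controls by 0.0548 and those of run D by 0.342, the latter being libraries on which the genes were picked, while the controls differed from RO replicates 4 to 7 by 0.232. An effect of run D alone therefore stays open. For 600 genes picked without run A, the RO library of run A scored -0.266 relative to the controls of run C, near the RO libraries of run B (-0.258 ± 0.16, SD, n = 6), on which the genes were picked. The control of run B scored -0.192, and the controls of run C ranged from -0.127 to 0.303. Control replicate 7 alone set that upper end, the next control of run C being at -0.00476. It also entered the mean of the run C controls, from which the scores are measured. An effect of run B alone stays open too, with 1 library on each side. Within run A, the median signed log2 difference of RA over RO on those genes was 0.298, whereas the scores are means over genes. By that median, 6 of 32 pairs of libraries from one group and run differed by as much. The RA and RO pairs among them are libraries on which the genes were picked, which tends to make their differences small.

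A hypothesis is that the axis between RA and RO may be one along which control animals also vary, such as tissue composition or RNA quality. The axis held 6.72% of the variance among the controls, against a median of 3.37% for other splits of the RA and RO libraries, and 9.03% of 1716 splits held as much, so the hypothesis was left open. Control replicate 7, labelled as a well-fed ovulating animal, scored 23.2 on the axis, among the RA libraries (-1.74 to 27.0). The other controls scored -10.7 to 1.93, so the variance among controls on this axis rested largely on that 1 library. The share was not computed without it. The mean correlation of control replicate 7 was 0.971 with RA and 0.958 with the other controls. Control replicate 6 also correlated better with RA (0.973) than with the other controls (0.966). Whether the label of control replicate 7 was exchanged was not tested.

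For RA against control, 14 of 100 splits gave as many genes under an unadjusted 0.05 as the real 1244, with 2963 for the highest other; for RO against control, 32 of 100 did, with 2873 against the real 864. Chance is thus not excluded for either. The highest splits called 525 and 316 genes at an adjusted 0.05, where the real splits called 0, and 2 and 3 of the other splits called any gene. The split with 525 calls set RA replicates 2, 5, 6 and 7 and control replicates 4, 5 and 7 against the others. Their scores on principal component 1 ran from -0.574 (control replicate 4) to 29.2, against -12.6 to 2.17 for the others. The split with 316 calls followed that component less closely, with RO replicate 1 at -7.33 on the side of control replicate 5. Whether a structure of the samples other than the study's groups lies behind these few splits was not tested. For the runs within RA, 6 of 35 splits gave as many genes as the real 1030, with 2514 for the highest other. In that highest split RA replicates 2, 5, 6 and 7 scored 4.01 to 20.6 on principal component 1. Replicates 1, 3 and 4, on its other side, scored -12.6 to -8.27.

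The counts were spread evenly at the upper end. The most abundant gene held 0.185% of a library's counts at most, the top 10 held 1.12% to 1.34%, and the highest mean of any gene was 1594 CPM. How duplicate or multiply mapped reads and mitochondrial genes were treated before deposit is not given in the sources used here, and the cause was not tested.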
